A study of Arabidopsis thaliana with 2 samples.

How the data were processed

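Total RNA from mature leaves of Arabidopsis thaliana was labelled with biotin and hybridised to ATH1 arrays, with 1 array of Col-0 wild type and 1 array of Pasta2M1.1, a line in the Col-0 background. Per the labels, seeds were kept in the cold and dark for about 84 h, plants were grown on MS plates and then in soil with 12 h of light at 43% relative humidity, and leaves were harvested on day 41. Only the labels of Pasta2M1.1 list 50 uM PPT in the plates. Groups were taken from the sample titles. No more replicates and no batch labels are given in the sources used here.

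The values deposited by the authors are signal intensities on a linear scale, 1 per probe set and array, made with MAS5, per the submitters' processing notes. MAS5 combines matched and mismatched probes into a background-corrected signal. Its version and settings are not given in the sources used here. The values themselves show that each array had been scaled to a common level: without the top and bottom 2% of probe sets, the mean signal was 100.0 on both arrays. Such scaling sets an array's overall level by convention, so a shift common to most transcripts would not be seen. Detection calls and probe-level intensities were not used here. As an estimate of background, 27 probe sets for Bacillus transcripts had a median signal of 1.8 on the Col-0 array and 2.1 on the Pasta2M1.1 array.

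Of 22810 probe sets, 64 controls were set aside. For the other 22746, the log2 ratio of Pasta2M1.1 to Col-0 was computed after adding 9.9 units, the 25th percentile of all signals, to each signal. This offset keeps dim probe sets from giving large ratios and pulls their ratios toward 0. Probe sets were compared when the mean of the signals was at least 37.8, its median, which left 11376. Counts of probe sets at 1.5, 2, 3 and 4-fold are descriptions of these arrays, since 1 array per group allows no test.

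Gene names came from the platform annotation, in which 13513 of these probe sets carry 1 gene, 503 carry several and 8730 are unnamed here. Probe sets with several genes were not named. Gene identifiers were matched to locus tags through a RefSeq gene table (assembly TAIR10.1), with 13436 matched. The build of the array design is not given in the sources used here. The RefSeq table was used for gene names and for the chromosome or plastid genome that a gene lies on. Its start positions were used only to order genes and so find which lie next to each other. Where a gene had several probe sets, the brightest was used, which gave 5976 genes.

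The genes to name were chosen by a rule fixed before the data were examined: the 12 genes with the highest and the 12 with the lowest ratio among probe sets that name 1 gene and whose type does not mark them as shared between transcripts, the SH2 domain genes, the highest and lowest members of lists that the text describes, and the reference genes ACT2, UBQ10, PP2AA3 and GAPC1. The last 4 genes and the SH2 domain genes are not reported because no probe set is named for them in the annotation used. Control probe sets for actin, GAPDH and ubiquitin and the reference genes UBC21, TIP41L and SAND are given in their place. Lists with few compared members are given in full. The unnamed probe sets past 2-fold are given without a name and were picked out after their values were seen.

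The 37 gene lists were also fixed before the data were examined. A list with at least 5 compared genes was described by the percentile of its median log2 ratio among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. A list was taken to stand apart below percentile 2.5 or at the same distance from the top. Only 1 list had enough members. Genes of a list are not independent, so this percentile describes these arrays and is not a p-value.

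The counting and the list percentile were tested on simulated data with a noise SD of 0.2 on the log2 scale. For simulated Pasta2M1.1 and Col-0 arrays of 11373 compared probe sets, the 2-fold count recovered 50 of 50 probe sets raised 3-fold and 50 of 50 lowered 3-fold. It also recovered 50 of 50 raised 4-fold and 50 of 50 lowered 4-fold, and took in 0 of 11173 unchanged ones. A 2-fold cut lies far outside this noise, so that count of 0 followed from the settings. It gives no error rate for real arrays, as the settings hold no term for differences between plants. In the data, the robust SD of log2 ratios fell from 0.219 in the dimmest compared probe sets to 0.135 in the brightest. Among 5970 simulated genes, 5 of 100 unchanged lists and 100 of 100 lists lowered by 0.4 stood apart. The shift of 0.4 is larger in size than the photosystem list's median log2 ratio of -0.09, and power at smaller shifts was not tested.

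Alternatives set before the data were examined were a common median, quantile normalization, removal of a lowess trend on brightness (fraction 0.3), no offset, an offset at the median signal, no brightness filter, a filter at the 75th percentile, leaving out shared probe sets, and the mean over a gene's probe sets. Scaling to the spike-in transcripts was added after seeing the data, as were common-median, lowess and spike-in scaling for the spread between probe sets of one gene. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9.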

Results

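Steady-state RNA was measured in mature leaves of Arabidopsis thaliana with ATH1 oligonucleotide arrays. A probe set on this array is a group of short probes summarised as 1 signal. There was 1 array of Col-0, the wild type, and 1 array of Pasta2M1.1, a line in the Col-0 background from a series about a gene with an SH2 domain, a protein module that binds phosphorylated tyrosine. Leaves were taken on day 41 after sowing in both groups. The labels list 50 uM PPT in the plates of Pasta2M1.1 only, so the line and this treatment cannot be told apart. The arrays had closely matched signal ranges, with a median signal of 38.1 for Col-0 and 37.2 for Pasta2M1.1 over 22746 probe sets that are not controls. The number of arrays limits the precision: with 1 per group no difference has a replicate check, and no p-value or standard error across plants is given.

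The comparison asked which transcripts differed in leaf RNA between Pasta2M1.1 and the wild type. QQS (AT3G30720), a small protein with a role in leaf starch and protein content, had a signal of 86.8 on the Col-0 array and 312 on the Pasta2M1.1 array, 3.33-fold higher. AT4G17470, of the palmitoyl protein thioesterase family, had 30.8 and 126.4, which is 3.35-fold higher. ARLA1C (AT3G49870), an ADP-ribosylation factor-like GTPase, had 224.9 and 62.0, which is 3.27-fold lower. These were the only probe sets past 3-fold among the 11376 bright enough to be compared, under the main scaling and offset. Folds are on the scale of the signal plus 9.9 units, which understates the change of dim probe sets. The plain ratios of the same signals are 3.59 for QQS, 4.1 for AT4G17470 and 3.63 for ARLA1C.

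At 2-fold, 3 probe sets were higher and 3 were lower in Pasta2M1.1, and 0 reached 4-fold. The other three at 2-fold carry no gene name in the annotation used. Of these, 1 was 2.04-fold higher, with signals of 23.5 in Col-0 and 58.4 in Pasta2M1.1. The others were 2.06-fold lower (66.8 and 27.4) and 2.03-fold lower (275.2 and 130.3). At 1.5-fold, 70 probe sets were higher and 64 lower, 1.18% of those compared. When the arrays were scaled to their spike-in transcripts, an alternative chosen after seeing the data, the split at 1.5-fold was 358 higher and 13 lower, and at 2-fold 11 higher and 1 lower. That scaling shifted the median log2 ratio of all compared probe sets by 0.23. With no offset the 2-fold counts were 9 higher and 8 lower.

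**Figure D1:**
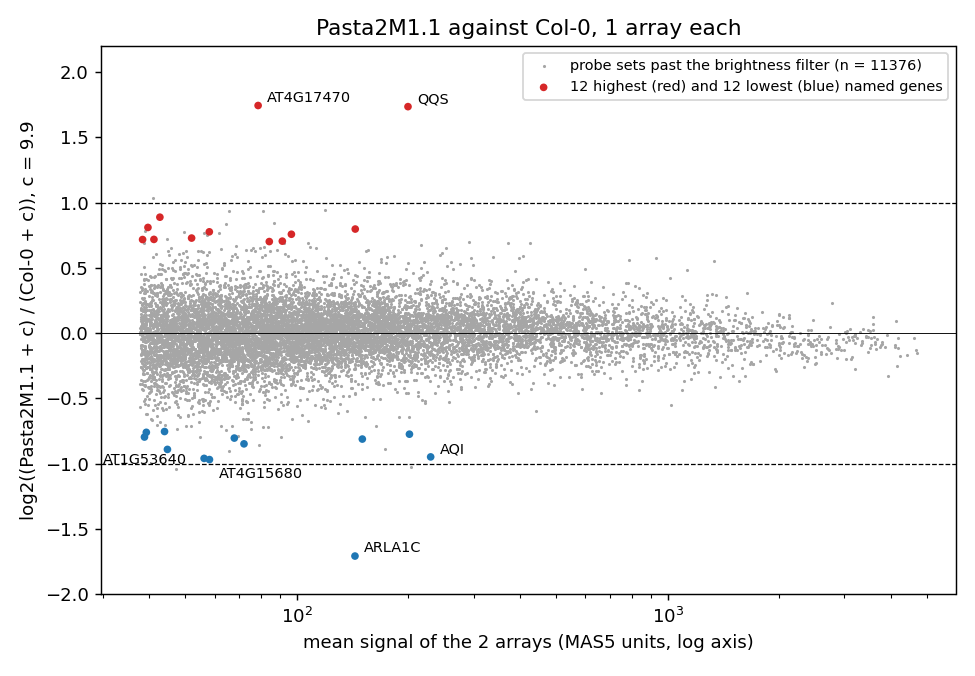
Log2 ratio of Pasta2M1.1 to Col-0 (vertical axis) against the mean signal of the 2 arrays in MAS5 units (horizontal axis, log scale) for 11376 probe sets, with 1 array per group. Red and blue points are the 12 named genes with the highest and the 12 with the lowest ratio, and dashed lines mark 2-fold. QQS and AT4G17470 lie at 1.74 and ARLA1C at -1.71, apart from the main body of points, whose robust SD is 0.17.

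After QQS and AT4G17470, the named genes with the highest ratios were each less than 2-fold higher in Pasta2M1.1 with the offset and the scaling as deposited. AT4G00955 and AT1G09500 passed 2-fold without the offset, and these and AT3G02190 passed it after spike-in scaling. AT4G00955 was 1.85-fold higher and AT1G09500, a cinnamyl-alcohol dehydrogenase-like protein, 1.75-fold higher. AT3G02190, of the ribosomal protein L39 family, was 1.74-fold higher, with signals of 102.3 and 185.1. AT2G23680, of the WCOR413 cold acclimation protein family, was 1.71-fold higher. AT4G16260, a glycosyl hydrolase of the beta-1,3-glucanase family, was 1.69-fold higher, with 69.3 and 124 units. SUFE2 (AT1G67810), a sulfur E protein of iron-sulfur cluster assembly, was 1.66-fold higher. The rest were AT1G27430, ZCF37 (AT1G59590), the short-chain dehydrogenase AT4G13180 and the 2-oxoglutarate-dependent dioxygenase AT2G38240, at log2 ratios from 0.70 to 0.72.

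Among the genes lower in Pasta2M1.1, AT4G15680, of the glutaredoxin family, was 1.96-fold lower than in Col-0, with signals of 80.1 and 36.1. AT1G53640 was 1.94-fold lower. AQI (AT4G38220), named aquaporin interactor, was 1.93-fold lower, with 305.5 and 153.6 units. AT5G62280 (61.1 and 28.4) was 1.85-fold and AT4G15640 1.80-fold lower. AT4G33380 was 1.75-fold lower, and so was AT3G49880, a glycosyl hydrolase and the gene next to ARLA1C. AT1G52180 (51.9 and 25.7) was 1.74-fold lower. LCB2 (AT5G23670), a subunit of serine palmitoyltransferase in sphingolipid synthesis, was 1.71-fold lower, with 256.5 and 145.9 units. The RNA-binding proteins AT1G13730 and AT2G41060 had log2 ratios of -0.76 and -0.75. Without the offset, AT4G15680, AT1G53640, AT5G62280 and AT1G52180 passed 2-fold, and after spike-in scaling ARLA1C alone of the lower named genes did.

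**Figure D2:**
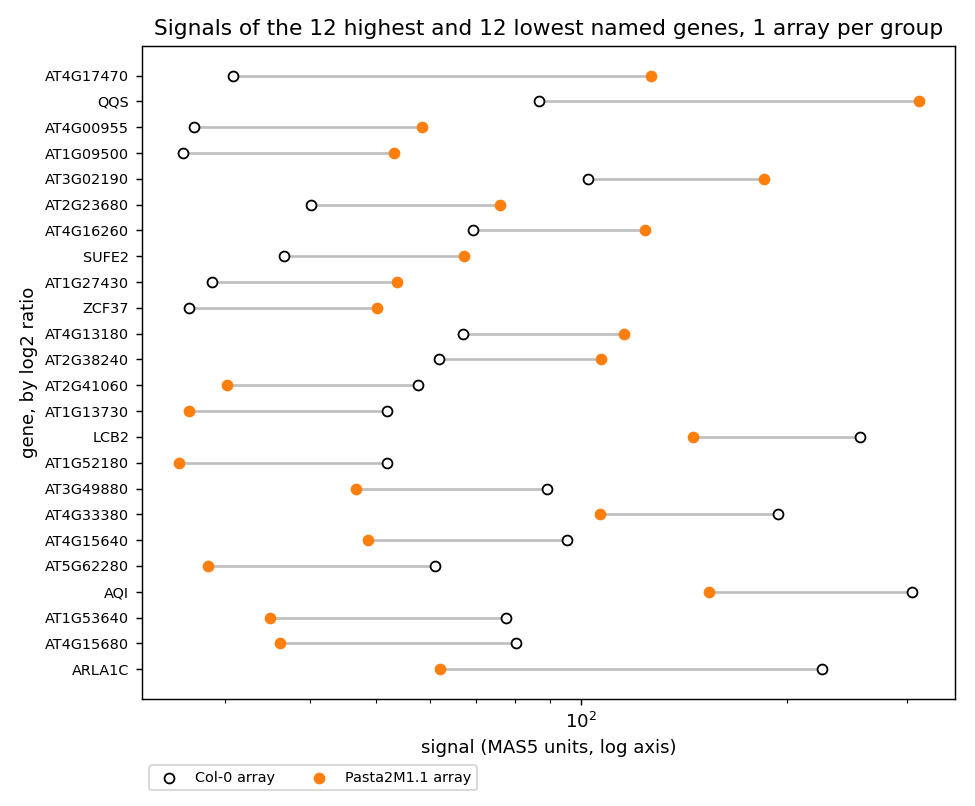
Signals in MAS5 units (horizontal axis, log scale) of the 24 named genes, ordered by log2 ratio, with an open circle for the Col-0 array and a filled circle for the Pasta2M1.1 array. Each point is 1 array with no replicate, so no error is drawn. QQS spans 86.8 to 312 units and ARLA1C 224.9 to 62.0 units.

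The gene that gives the series its subject is not analysed here. The labels give no locus for it, and 0 of the 3 SH2 domain loci fixed in advance (SHA, SHB and SPT6L) is named by a probe set in the annotation used. Of 488 loci in 37 lists fixed in advance, 64 are named on the array and 39 were bright enough to be compared. Of these 39, 0 differed by 1.5-fold or more; 16 were higher, 22 lower and 1 equal in Pasta2M1.1. Under spike-in scaling, which raises nearly all ratios together, 17 of the 39 changed sign, all from lower to higher.

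Photosystem and light-harvesting genes were the 1 list with at least 5 compared members. Of its 40 loci fixed in advance, 7 are named by a probe set of their own, and all 7 were compared. Of these 7, 5 were lower and 2 higher, with a median log2 ratio of -0.09. LHCB4.2 and PSBW turned positive after quantile normalization, and all 5 did after spike-in scaling. PSAN, a photosystem I subunit, had -0.14 and ATPC1, the gamma subunit of the chloroplast ATP synthase, -0.11, while LHCB4.3, a minor antenna protein, had 0.12 and PSAE-1 0.01. The median lay at percentile 8.83 of 10000 random lists matched on brightness, so the 7 compared genes did not stand apart. The loci of this list without a name were not examined. After quantile normalization the list's median was 0.00 at percentile 45.6. Spike-in scaling, which raises the compared probe sets by similar but not equal amounts, gave a median of 0.16 at percentile 9.3. The Calvin cycle genes RCA, SBPASE and PRK, 3 of 16 loci in that list, had -0.20, -0.18 and -0.16. The photorespiration genes GLYK, GDCT and HPR, 3 of 12 loci, had -0.24, -0.13 and -0.08. All of these except GLYK were above 0 under spike-in scaling.

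Stress and defence lists held few compared members, mostly because few of their loci are named. Named were 3 of 26 salicylic acid, 4 of 27 jasmonate and 0 of 13 ethylene loci. The defensins PDF1.2 and PDF1.2b, markers of jasmonate and ethylene signalling, had signals of 247.3 and 217.9 in Col-0 and 316.8 and 287.4 in Pasta2M1.1, log2 ratios of 0.35 and 0.38. The PDF1.2b probe set is of a type that can bind related transcripts, so the pair may not be separate measurements. In the salicylic acid list, WRKY53 had 0.26 and SAG101 0.01. LTI30, a dehydrin of the abscisic acid and drought list, was 1.44-fold higher, with 243.1 and 353.3 units. The cold-response genes COR15B and COR47 had 0.14 and 0.09, and COR15A had -0.01, a sign that turned under every other scaling tried. The heat shock genes FKBP65 and HSP15.7 had -0.54 and -0.43, with FKBP65 at 70.5 and 45.5 units. ERDJ3B, an endoplasmic reticulum chaperone, had 0.13 and the antioxidant list's UPOX -0.28.

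In metabolism and development, DPE1, a disproportionating enzyme of starch breakdown, was 1.44-fold lower in Pasta2M1.1, with signals of 305.6 and 208.6. BCAT4 and UGT74C1, of aliphatic glucosinolate synthesis, had log2 ratios of 0.29 and 0.09, and UGT74B1 of the indolic list 0.10. The flavonoid glycosyltransferases UGT78D1 and UGT78D2 had 0.24 and 0.00. Single compared members were IAA29 of the auxin list at -0.16, ARR16 of the cytokinin list at -0.05, GI of the evening clock at -0.04, STZ of touch and wounding at -0.13, and FAMA of guard cells at -0.17. All of these 5 were above 0 under spike-in scaling.

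Of the other lists, 7 had named members but 0 bright enough to be compared, and 10 had no named member. Of the leaf senescence list, SAG29 had signals of 21.0 in Col-0 and 3.1 in Pasta2M1.1, and WRKY6 had 13.6 and 24.4. The root markers EXPA7, EXPA18 and PYK10 had signals of 10.8, 12.6 and 8.0 on the Col-0 array, where the highest of 27 control probe sets for Bacillus transcripts was 8.0. On the Pasta2M1.1 array they had 7.7, 4.0 and 5.7, where the highest of these controls was 12.8. Few loci of the detoxification (3 of 21), iron (1 of 10), sulfur (1 of 9), dividing cell (1 of 12) and trichome (1 of 4) lists are named. These named members likewise fell below the brightness filter. The other loci of these lists have no named probe set of their own in the annotation used, so they were not examined.

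Reference genes and control probe sets give the error that can be measured within these arrays. UBC21, TIP41L and SAND had log2 ratios of 0.04, 0.23 and -0.13, and SAND was above 0 under spike-in scaling. The 16 control probe sets for actin, GAPDH and ubiquitin had a median of 0.03 and a range from -0.13 to 0.20. All 18 spike-in probe sets (BioB, BioC, BioD and Cre) were lower on the Pasta2M1.1 array, with a median of -0.24. What caused this shift in the spike-in signals was not tested. The direction of negative ratios smaller in size than this shift can depend on the scaling, though GLYK, at -0.24, stayed just below 0. For 52 genes with a pair of compared probe sets, the pair's log2 ratios differed by a median of 0.18. When partners were exchanged between genes, the median difference was 0.19, with 95% of exchanges between 0.14 and 0.24. Across these 52 genes, which are not independent replicates, Pearson's r between partners was 0.23 (permutation p = 0.105, two-sided) and Spearman's rho 0.09 (permutation p = 0.509, two-sided). Without the 2 genes farthest from the median, r was 0.00.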

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

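Chosen after the data were seen were the spike-in scaling and, for the spread between probe sets of one gene, the common-median and lowess scalings; the other alternatives were set before. Counts moved by over 1.5 times where the treatment of dim probe sets changed. Without the offset, 9 probe sets were 2-fold higher and 8 lower, and 109 and 132 passed 1.5-fold. With the offset at the median signal, 1 was 2-fold lower, and 15 and 14 passed 1.5-fold. Without the filter, 56 were 2-fold higher and 101 lower, 491 and 871 passed 1.5-fold, and the spread between probe sets of one gene was 0.22. With the filter at the 75th percentile, 1 was 2-fold higher, and 14 and 13 passed 1.5-fold, with fewer probe sets compared. Scaled to the spike-ins, 11 were 2-fold higher and 1 lower, and 358 and 13 passed 1.5-fold. The photosystem list's median was 0.00465 after quantile normalization, -0.0314 after removing the lowess trend and 0.156 after spike-in scaling; the cause was not tested. That list stood apart under none of the alternatives run.

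Of the 6 probe sets past 2-fold, 6 stayed past it under quantile, 6 under lowess, 5 under common-median and 4 under spike-in scaling, 6 without the offset and 3 with the larger offset. Across those settings QQS ranged from 1.49 to 1.96, AT4G17470 from 1.26 to 2.04 and ARLA1C from -1.86 to -1.40. For the 24 named genes, 64 of 96 recomputed ratios moved by less than 0.184 and 32 moved by more. This yardstick is an SD scaled from the median difference between probe sets of one gene. It holds no difference between plants, and a small move shows only that the rescaling was small. The larger moves came from spike-in scaling, where every named gene moved by more, and from leaving out the offset, where some did. Under quantile and lowess scaling every named gene moved by less. These genes were chosen for large ratios, so their direction was not at stake. Without the filter, the heat shock and flavonoid lists reached 5 and 6 genes and lay at percentiles 18.6 and 40.9. The SH2 domain alternatives were not run, since no probe set is named for those genes. No paired analysis was possible because the groups share 1 replicate number with 1 array each. Signals near the Bacillus controls (up to 12.8 units) limit what can be read for dim genes.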

Other observations

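Chosen after the results were seen were the gene groups described here and the tests of RNA quality, nuclear photosynthesis genes and ARLA paralogs; the tests of the lowess trend and of chance neighbours were set before their results.

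Signals for transcripts encoded in the plastid genome were slightly lower in Pasta2M1.1 as deposited, though most were higher after spike-in scaling. Whether these signals follow the amount of plastid RNA was not tested. Of 65 compared plastid genes, 52 were lower, 12 higher and 1 equal, with a median log2 ratio of -0.09. After quantile normalization 44 were lower and 21 higher, and after removing the lowess trend 46 and 19. The photosystem genes had the lowest median of the 6 functional groups, -0.19 over 20 genes, of which 16 were lower. Its genes, picked out after their values were seen, ran from psbN at -0.62 to psbF at 0.06 and psbE at 0.11. psbN was among the dimmer compared probe sets, with signals of 65.8 and 39.4. Next lowest in this group were psbD (signals 534.6 and 351) at -0.59 and psbC (1215.6 and 827.2) at -0.55. psbA, which encodes the D1 protein, had -0.43. Genes for plastid ribosomal proteins had a median of -0.08 over 14 genes, and those of the NDH complex -0.04 over 9. Under spike-in scaling 49 of the 65 were above 0, with a median of 0.15 against 0.24 for matched nuclear lists, a shift common to both that is no separate test of their difference. Mitochondrial nad, cox, ccb and matR genes, 5 of which were compared, had a median of 0.12.

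Families sharing a symbol stem were described for every stem with at least 8 compared genes. Of 10 such families 0 stood apart, where chance would give 0.5. The glycosyltransferases of the UGT family, with 18 genes, had a median of -0.02, from -0.53 for UGT85A4 to 0.25 for UGT71B1. The prenylated RAB acceptors of the PRA1 family, with 9 genes, had a median of 0.12 at percentile 95.6. Of 8 autophagy (ATG) genes, 6 were higher and 2 lower, with a median of 0.07 at percentile 88.9, from -0.48 for ATG8G to 0.40 for ATG8H. These are single ratios with no replicate check, and spike-in scaling, which shifts the median of all compared probe sets by 0.23, turns the smaller negative ones positive.

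The lower plastid signal was weighed against technical explanations. A trend with brightness as the whole cause is argued against, since after the lowess trend was removed the plastid median stayed at -0.07, at percentile 0 of 10000 matched nuclear lists. Lists matched on brightness gave percentile 0 with the signals as deposited too, so removing the trend added little. Plastid genes are not independent of each other, so this percentile is not a p-value. The RNA-quality test, of more degraded RNA in Pasta2M1.1, was open. By its rule only a lower 3' to 5' ratio in Pasta2M1.1 could have counted against this. The 6 ratios of 3' to 5' probe sets had a median log2 change of -0.0173, within their SD of 0.10, so no clear change was seen. The changes ran from -0.09 to 0.18. They came from actin, GAPDH and ubiquitin, with more than 1 ratio per transcript, so they are not independent checks. A hypothesis is that photosynthesis genes of both genomes were lower in Pasta2M1.1, and 13 nuclear genes of the photosystem, Calvin cycle and photorespiration lists together lay at percentile 0.415. These lists were put together after their results were seen, so this percentile is no separate support for the hypothesis. The low percentile of these nuclear genes rests on the scaling, as it was 24.6 after quantile normalization and 3.70 after removing the lowess trend. Spike-in scaling left it at 0.555. That scaling raises nearly all ratios together, so 12 of the 13 were then higher, with a median of 0.14 against 0.24 for matched lists. Leaf stage, RNA preparation, the line and PPT stay open and were not tested.

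ARLA1C and its neighbour AT3G49880 were both lower in Pasta2M1.1, the 1 pair of 1475 compared neighbours in which both genes were at least 1.5-fold lower. For ARLA1C, signal shared with paralogs is argued against, as ARLA1A and ARLA1D had log2 ratios of 0.09 (the lower of them, at 0.0857) and 0.33. This comparison was set after the results were seen, and it does not bear on AT3G49880. Chance remains open: when values were permuted among genes, a share of 0.065 of 10000 permutations held at least 1 pair with both genes 1.5-fold lower. Beyond AT3G49880, the genes AT3G49890 and AT3G49900 were too dim to compare, AT3G49910 and AT3G49930 both had 0.01, and ARLA1B on the other side was at 5.2 and 4.1 units, too dim to compare. A lesion or linked difference at this locus in the line is a candidate explanation that was not tested.

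QQS and AT4G17470 had the highest log2 ratios among compared probe sets, both 1.74, and ARLA1C had one of like size in the other direction, -1.71. Without the offset QQS and AT4G17470 had 1.85 and 2.04, and with the larger offset 1.49 and 1.26. QQS is known to vary between Arabidopsis plants through heritable differences in DNA methylation, so a difference between seed stocks may be enough, and this was not tested. A local fault of an array cannot be excluded without probe-level values or a replicate.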
